A study of Drosophila melanogaster with 3 samples.

How the data were processed

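Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole *Drosophila melanogaster* prepupae carrying an insertion that makes a CG6163-eGFP fusion protein, with an antibody against GFP. Per the labels, 3 libraries were biological replicates of this single group, and chromatin was sonicated to fragments of 200 to 800 bp. The control experiment that the labels name was not used here, and no other condition was part of the comparisons.

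The deposited files are peak lists on the dm6 assembly, in which each line holds a position, a summit and values per peak. Per the labels and the notes deposited with the lists, each library's list was derived from its own alignment, the lists of the whole series from all 3 libraries, and every list also from 1 shared file. The aligner and the peak caller are not given in the sources used here. The authors filtered the lists by the irreproducible discovery rate (IDR), which measures how well the ranks of peaks repeat between sets. A score per peak that rises as the IDR falls, deposited by the authors, began at 830 in every thresholded list. The signal per peak, as deposited by the authors, is a value of one list. It was used to rank or describe peaks within that list, and to correlate signal between the replicates' ranked lists. For weak peaks it was also set beside the signal of library peaks. The −log10 values deposited by the authors for the q-value and the IDR were used only as filters. A q-value above 0.05 applied to 33.7% of the conservative list. Columns of the ranked lists that hold values of the compared sets were not used. The number of reads per library was not used here, so depth is given as the number of peaks.

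The main set was the series list named conservative, with 10894 peaks, of which 10892 lay on chromosomes 2L, 2R, 3L, 3R, 4 and X. Genes came from the Ensembl annotation with dm6 coordinates, without its transposable elements, and sequence came from the RefSeq release of the same assembly. Of the peak ends on the main chromosomes and Y, 0 lay beyond the chromosome lengths of that assembly. A promoter was the stretch within 500 bp of an annotated transcript start of any gene. Each summit was given 1 class, in the order promoter, 5' UTR, 3' UTR, coding exon, other exon, intron, intergenic. Shares were compared with 1000 random placements of the peaks on their own chromosome (two-sided permutation test, Benjamini-Hochberg over classes). The smallest two-sided p these placements can give is 0.002, and the smallest one-sided p is 0.001. Overlap between replicates needed 1 bp in common and was tested with 1000 placements, one-sided. Intervals are exact binomial 95% intervals and cover counting error only.

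A protein-coding gene was called bound when a summit lay within 500 bp of any of its transcript starts. The share of bound members of 24 gene lists was compared with that of all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over lists and a threshold of 0.05. Genes rather than animals are the units of that test. It describes these peak lists. Of the list members, EcI, wd and don matched no annotated symbol, an older symbol pattern for RNA polymerase subunits matched none, and Toll was already present as Tl. Older symbols were otherwise replaced by current ones. Presence of 26 motifs, fixed as consensus sequences, was compared between windows reaching 50 bp to each side of the summit and equal windows centred 300 bp away (exact sign test, two-sided, Benjamini-Hochberg over motifs). All 8-base words were ranked by the same test on 2L and 2R, and the 10 best were retested on the other chromosomes. Peaks within 20 kb of CG6163 were counted against the surroundings of 1000 random protein-coding genes (permutation test, one-sided).

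Genes were named by a fixed rule. It took the 12 genes with the highest signal among conservative peaks at protein-coding starts that overlapped a thresholded peak in all 3 libraries, up to 3 bound members of each list by signal and up to 2 unbound members in alphabetical order, CG6163, and the 5 strongest peaks. The gene lists, motifs, tests, naming rule and most alternative settings were fixed before the data were examined. The alternatives changed the overlap rule, the IDR limit, the peak list, the promoter window, the background, the sequence windows and the replicates used. The preset IDR limit of 0.01 removed no peak because the deposited lists already began near it, so a limit of 0.001 was added after the data were seen. A q-value limit of 0.05, 1 peak per merged region and shuffled windows for the words were also added then.

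Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data. A simulated set with 48.7% of summits at promoters, planted or by random placement, was classed as 48.7%. Both values used the same summits and annotation, so this checks only the assignment of classes. Of 100 unplanted sets, 5% had a p under 0.05. A list with planted binding was called in 100 of 100 simulations over 13945 genes, while 0.391% of the tests of other lists made a call. Simulated binding did not depend on the number of transcript starts, whereas in the data genes with more starts were bound more often. That rate of calls therefore need not hold for the data. A planted motif was called and no other motif was. The planted 8-base word ranked 1, the 9 other words called all shared at least 6 bases with it, and 0 words were called in unplanted windows. These simulated windows lay at random positions, where summit and flank do not differ in composition. In the data summits were 60.9% A/T against 57.0% in flanks. The motif and word simulations therefore do not give the rate of false calls in the data.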

Results

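The CG6163-eGFP fusion protein was mapped in chromatin of whole prepupae, the stage at which the larva becomes a pupa, in 3 biological replicates of 1 group. Thresholded peaks numbered 7449 in replicate 1, 7920 in replicate 2 and 5844 in replicate 3, which is 7071 ± 1090 (SD, n = 3). The conservative list, the main set here, held 10894 peaks with a median width of 370 bp. The notes name all 3 libraries as its sources but not which replicates were compared to make it. Signal values below are the authors' values per peak in that list unless a replicate is named, and all coordinates are dm6.

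The same sites were found in the 3 replicates far more often than by chance. Of the peaks of replicate 3, 79.8% overlapped a peak of replicate 1 and 81.7% a peak of replicate 2. Of the peaks of replicate 1, 78.2% overlapped replicate 2 and 63.2% replicate 3, and of those of replicate 2, 73.9% overlapped replicate 1 and 61.0% replicate 3. The mean over these 6 ordered pairs was 73.0% ± 8.82 (SD over pairs), against 2.81% for randomly placed peaks (permutation test, one-sided, p = 0.001 in each pair, the smallest possible). In the conservative list 4385 peaks overlapped a thresholded peak in all 3 replicates, 2320 in 2 replicates, 2061 on the main chromosomes in 1 and 2126 in none. Among the strongest 10% of peaks, 99.3% overlapped a peak in all 3 replicates. The signal of the same peaks correlated between replicates with Spearman coefficients of 0.825 for replicates 1 and 2, 0.769 for replicates 1 and 3 and 0.773 for replicates 2 and 3. These coefficients are across peaks, which are not independent replicates.

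Peaks lay at gene promoters and in introns and avoided coding sequence. Promoters held 35.7% of the summits (95% interval 34.8 to 36.6), which was 2.63 times the 13.5% of random placement. The replicates' own lists gave 38.3% ± 1.13 (SD, n = 3). Introns held 44.0% against 39.4% at random, and intergenic sequence held 16.7% against 27.3%. Coding exons held 0.762% against 13.0%, a 17.1-fold shortfall, and 3' UTRs held 0.790% against 5.05%. The permutation test gave an adjusted p of 0.002, the smallest possible, for each of these classes and for the 5' UTR (1.16% against 0.779%), and 0.214 for other exons (0.927% against 0.816%). Ranked peaks that passed no threshold had 12.5% of their summits at promoters and 19.9% in coding exons, and against these peaks the 5' UTR share no longer differed (Fisher's exact test, p = 0.232).

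**Figure D1:**
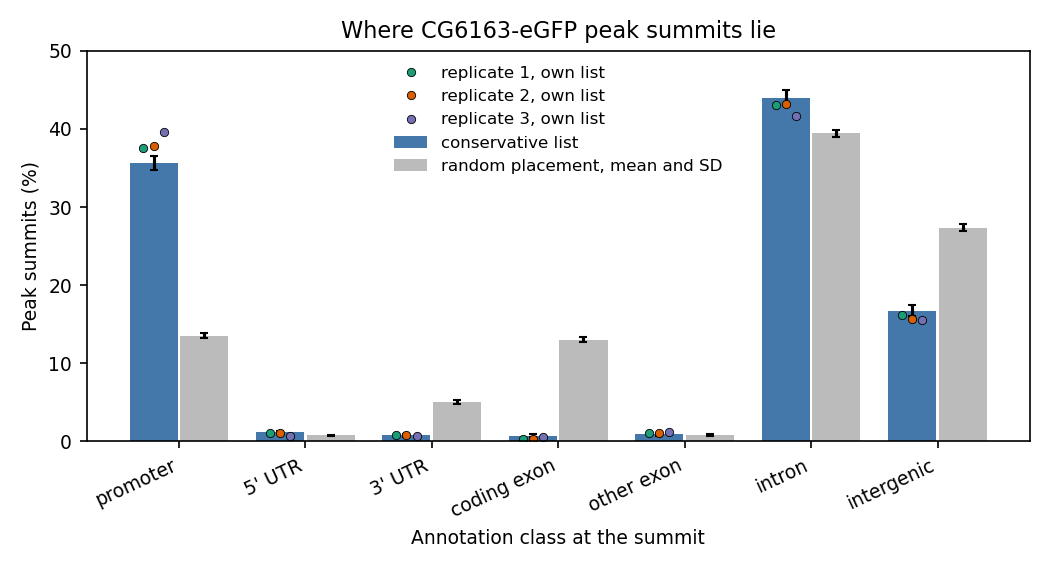
Share of peak summits (%) in each annotation class for the conservative list (blue bars, exact 95% intervals), random placement (grey bars, mean and SD of 1000 placements) and the own list of each replicate (points). Promoter summits stand at 35.7% against 13.5% at random, and coding-exon summits at 0.762% against 13.0%.

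Within promoters, summits lay more often upstream than downstream of the transcript start. Of the 3884 promoter summits, 2505 lay upstream of the nearest start and 1369 downstream, so that 64.7% were upstream (95% interval 63.1 to 66.2), against 45.2% of random placements inside promoters. The median promoter summit lay at −61 bp, while the median distance of all summits to the nearest start was 1234 bp. The median signal was 147 at promoters, 138 in introns, 133 in intergenic sequence and 83.3 in coding exons. The strongest 10% of peaks had 43.2% of their summits at promoters and none of 1090 in coding exons.

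**Figure D2:**
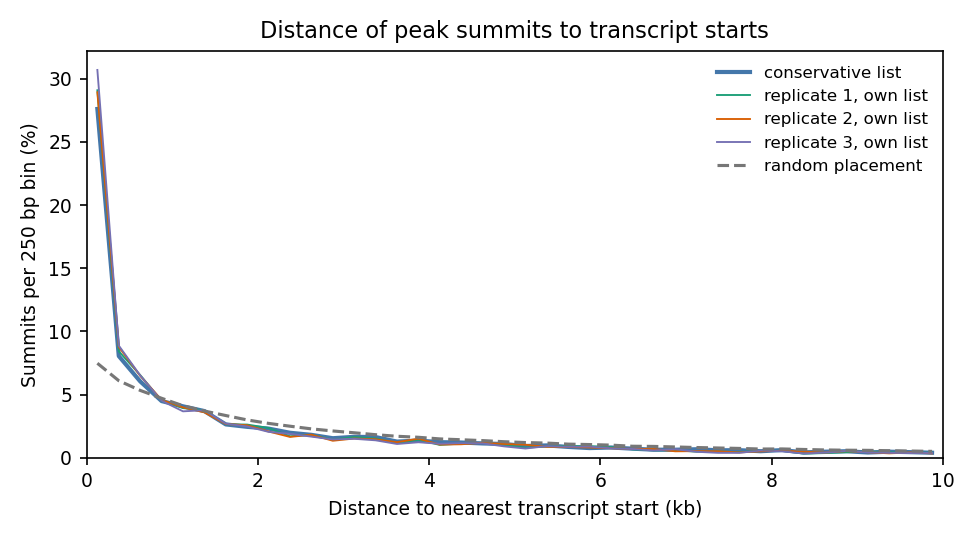
Share of summits (%) per bin of 250 bp against the distance to the nearest transcript start (kb), for the conservative list, each replicate's own list and random placement (dashed). The conservative list and all 3 replicates exceed random placement in the bins nearest the start, where promoters within 500 bp hold 35.7% of the conservative summits.

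The strongest promoter peak lay at *Ugalt*, and 2 of the 12 genes with the highest signals encode mitochondrial ribosomal proteins. The highest signal in the list, 4494, was at X 2703723 to 2704055, 39 bp from the start of *Ugalt*, which encodes a transporter of UDP-galactose into the Golgi. *CG14100* followed with 3766 (3L 19590459 to 19590764), then *PNPase*, the polynucleotide phosphorylase of mitochondrial RNA, with 3117 (3R 31404510 to 31404816), and *CG7601* with 3009 (3R 29736691 to 29736995). *CenG1A* had 2935 (2L 13835316 to 13835616), in a peak that also lay at the start of the mitochondrial ribosomal gene *mRpS23*. *Tcs5* (2888), *CG18549* (2796), *mRpS10* (2610), *mRpL41* (2561), *ph-p* (2531), *CG3552* (2461) and *CG9147* (2457) completed the 12 genes. *ph-p* encodes Polyhomeotic, a subunit of a Polycomb repressive complex, and its summit was 490 bp from the start, while the summits of the others were 2 to 131 bp away. Each of these peaks overlapped a thresholded peak in all 3 replicates. Of the 5 strongest peaks, 4 belonged to this group, and the other lay in an intron of *CG11050* at 2L 6612372 to 6612977, 1025 bp from the nearest start, with a signal of 4374. The summit at *PNPase* lay inside the gene, and those at *Ugalt*, *CG14100* and *CG7601* lay inside no annotated gene.

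Promoters of ribosomal protein genes, ecdysone-response genes, developmental signalling genes, autophagy genes and Hox and segmentation genes were bound more often than those of other genes, and promoters of cuticle, digestive-enzyme and testis-specific genes less often. Of 13945 protein-coding genes, 3371 (24.2%) had a bound promoter, and the replicates' own lists bound 2595 ± 170 genes (SD, n = 3). Of the 24 lists, 5 were higher and 3 lower at an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg), and 16 were not past the threshold. Against random lists matched on transcript starts and gene length, 4 of these calls were kept. The ecdysone-response, Hox and segmentation, digestive-enzyme and testis-specific calls were lost there. With only the peaks shared by all 3 replicates, or shared by the remaining replicates when replicate 1 or replicate 2 was left out, only the ribosomal protein and cuticle lists kept their calls. Without replicate 3, the Hox and segmentation and the testis-specific lists lost theirs, the latter with a log2 odds ratio of −3.12 ± 2.06 (SE; 0 of 24 bound) against −2.32 ± 1.22 in the main test (1 of 24 bound), and the circadian clock list was called.

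The cytoplasmic ribosomal proteins, which build the ribosome of the cytosol, had 63 of 93 members bound (67.7%, 95% interval 57.3 to 77.1), against 23.9% of other genes. The log2 odds ratio was 2.73 ± 0.32 (SE), and the replicates' own lists gave 63.8% ± 3.10 (SD, n = 3). *RpL7* (signal 676), *RpS27* (660) and *RpL32* (581) were the strongest, and *RpL10* and *RpL10Aa* were among the unbound members. This list kept its call with only the 4385 peaks found in all 3 replicates, where 50 of 93 members were bound (exact adjusted p = 5.66e-21).

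Ecdysone is the steroid hormone that drives metamorphosis, and 22 of 35 genes of its response were bound (62.9%, exact adjusted p = 7.72e-06). They included *E23* (signal 1001), an ecdysone-inducible transporter, *Eip93F* (664), an ecdysone-induced transcription factor, and the nuclear receptor gene *Hr3* (422). *Cyp18a1*, whose product inactivates ecdysone, and *Cth* were unbound. The replicates' own lists bound 45.7% ± 10.3 of the list (SD, n = 3). Random lists matched on transcript starts and gene length had 16.9 bound members on average and ended the call (permutation adjusted p = 0.178). With only the peaks found in all 3 replicates, 9 of 35 members were bound (25.7%, against 12.1% of other genes; exact adjusted p = 0.181), a log2 odds ratio of 1.38 ± 0.55 (SE) against 2.39 ± 0.50 in the main test.

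Genes of the Notch, Wnt, Hedgehog, Dpp and EGFR pathways, which pattern developing tissue, had 28 of 46 members bound (60.9%, exact adjusted p = 9.85e-07). The strongest were *spi* (signal 529), a ligand of the EGF receptor, *numb* (472), an inhibitor of Notch, and *nkd* (405), an inhibitor of Wnt signalling. *Axn* and *H* were unbound. The autophagy list had 13 of 23 members bound (56.5%, exact adjusted p = 0.00300), led by *Atg2* (460), *Atg17* (353) and *Atg18a* (310). Hox and segmentation genes had 21 of 42 members bound (exact adjusted p = 0.00151), led by *Dll* (1288), a homeobox gene of limb development, *hb* (958) and *cad* (324), with *Dfd* and *Kr* unbound. The signalling and autophagy lists stayed past the threshold against matched random lists (permutation adjusted p = 0.0110 for both), and the Hox and segmentation list did not (adjusted p = 0.158). With only the peaks found in all 3 replicates, these 3 lists were not past the threshold (exact adjusted p = 0.364, 0.205 and 0.433). The log2 odds ratio was then 0.68 ± 0.55 (SE) for signalling, from 2.28 ± 0.43, and 0.62 ± 0.58 for Hox and segmentation, from 1.66 ± 0.44. For autophagy it was 1.43 ± 0.66, from 2.02 ± 0.59, with 26.1% bound against 12.1% of other genes. The autophagy call was also lost on the series lists of 9110 and 8933 peaks (exact adjusted p = 0.0558 and 0.0529) and with the nearest start within 5 kb (exact adjusted p = 0.304). The Hox and segmentation call was lost on the same 2 series lists and, in alternatives added after the data were seen, at an IDR limit of 0.001 and at a q limit of 0.05.

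Cuticle genes, which encode the proteins of the insect exoskeleton, had 5 of 124 members bound (4.03%, exact adjusted p = 2.55e-08), of which *Cpr97Eb* (signal 137), *Cpr73D* (103) and *Cpr51A* (90.3) were the strongest. The replicates' own lists bound 1.34% ± 1.23 (SD, n = 3). None of the 124 was bound by a peak found in all 3 replicates (exact adjusted p = 2.46e-06). Midgut digestive enzymes had 1 of 45 members bound, *Mal-A5* (signal 1045), with an exact adjusted p of 0.000395. Testis-specific genes had 1 of 24 bound, *Mst87F* (115), with an exact adjusted p of 0.0498. That call was lost with a promoter window of 200 bp (log2 odds ratio −1.82, exact adjusted p = 0.184). In alternatives added later it was lost at an IDR limit of 0.001, at a q limit of 0.05 and with 1 peak per merged region. The exact adjusted p was 0.0775, 0.139 and 0.0501 there. The log2 odds ratio was −3.32, −1.89 and −2.32, against −2.32 in the main test. Against matched random lists, the cuticle list remained lower (permutation adjusted p = 0.00360), and the digestive-enzyme and testis lists did not pass the threshold (adjusted p = 0.158 and 0.261). With only the peaks found in all 3 replicates both calls were lost, with log2 odds ratios of −2.04 ± 1.20 (SE) for digestive enzymes, from −3.25 ± 1.20, and −2.76 ± 2.06 for testis-specific genes, from −2.32 ± 1.22.

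The other 16 lists did not pass the threshold against other genes. Mitochondrial ribosomal proteins had 22 of 73 members bound (30.1%, exact adjusted p = 0.401) and included 3 genes at the strong peaks named above. Against matched random lists, which had 8.40 bound members on average, that list was higher (permutation adjusted p = 0.00240), but it was lower than other genes when a gene was called bound by having the nearest start within 5 kb of a summit (log2 odds ratio −1.36, exact adjusted p = 0.0102). Also higher than matched lists was the transcription and splicing machinery with 21 of 72 bound against 12.8 (permutation adjusted p = 0.0432). The muscle list (5 of 26 bound against 12.3) and the neuronal list (4 of 25 bound against 13.5) were lower than matched lists, with permutation adjusted p-values of 0.00576 and 0.00320. In the neuronal list, *elav* (855), *Sh* (282) and *comt* (138) were bound, and in the muscle list *Msp300* (564), *sls* (453) and *Mef2* (255). *MED30* (461), *Polr2H* (435) and *Taf5* (414) led the transcription and splicing list.

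Circadian clock genes had 6 of 11 members bound (exact adjusted p = 0.0702), among them *sgg* (signal 845). They were called higher on the series list of 12445 peaks and at a q limit of 0.05 (exact adjusted p = 0.0272 and 0.0314). Without replicate 3 they were also called higher (exact adjusted p = 0.0132). Matched random lists had 4.88 bound members on average, and against them the circadian list was not past the threshold (permutation adjusted p = 0.847). Nor was it with only the peaks found in all 3 replicates (36.4% bound against 12.1% of other genes, exact adjusted p = 0.181). Polycomb and Trithorax genes had 10 of 26 bound (exact adjusted p = 0.183), with *brm* (1463), the ATPase of a chromatin remodelling complex, and *ph-d* (519) after *ph-p*. Chromatin architecture genes had 6 of 21 bound (exact adjusted p = 0.641), with *Chro* (2228), *Trl* (682), which encodes the GAGA factor, and *Cp190* (626), while *CTCF* and *Clamp* were unbound. Heat shock genes had 8 of 23 bound (exact adjusted p = 0.366), with *Hsp27* (2450), *Hsp83* (747) and *Hsp26* (690). Immune genes had 10 of 30 bound (exact adjusted p = 0.401), led by *imd* (1004), and cell death genes 5 of 15 (adjusted p = 0.453), led by *hid* (363). Fat body and larval serum protein genes had 5 of 14 bound (exact adjusted p = 0.439), with *Lpin* at 1909, and cell cycle and replication genes 10 of 34 (adjusted p = 0.596), with *Dp* at 736. Oxidative phosphorylation genes had 14 of 87 bound (exact adjusted p = 0.159), led by *ND-ASHI* (1117), and proteasome genes 6 of 48 (adjusted p = 0.137), led by *Rpn3* (433). With a promoter window of 1000 bp the proteasome list was called lower (exact adjusted p = 0.0402). With the nearest start within 5 kb the proteasome and oxidative phosphorylation lists were both called lower (exact adjusted p = 0.0480 and 0.0206). Against matched random lists, with 8.49 and 17.0 bound members on average, neither was past the threshold (permutation adjusted p = 0.677 for both). Ecdysteroid synthesis genes had 1 of 17 bound, *shd* (109), with an exact adjusted p of 0.169. Salivary glue and late puff genes had 1 of 22 bound, *Sgs8* (87.6), with an exact adjusted p of 0.0686. That peak overlapped a thresholded peak in 0 replicates, and the replicates' own lists bound none of this list. The list was called lower in 4 alternatives: with the nearest start within 5 kb, on the series lists of 12445 and 8933 peaks, and at a q limit of 0.05 (exact adjusted p of 0.00436 to 0.0412). Matched random lists had 1.97 bound members on average, and against them the list was not past the threshold (permutation adjusted p = 0.953).

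**Figure D3:**
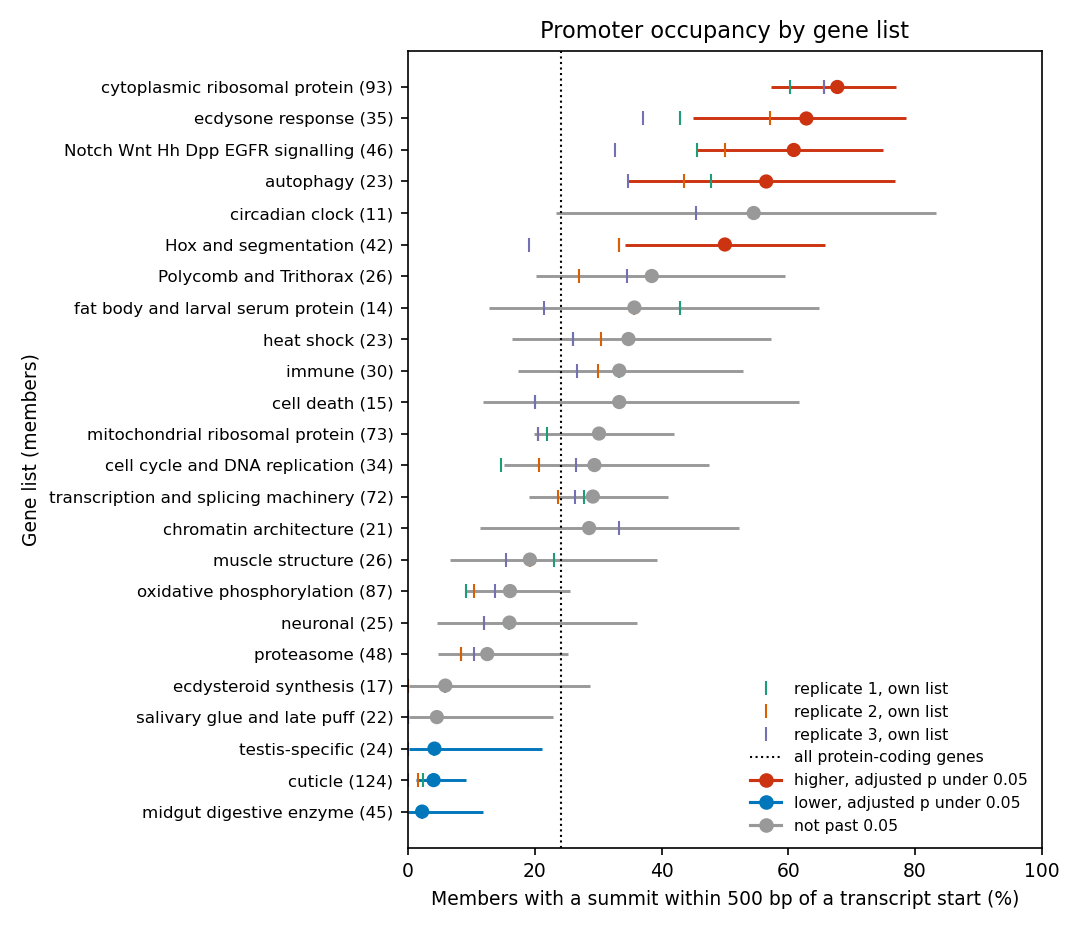
Share of members (%) with a summit within 500 bp of a transcript start for each of the 24 gene lists (number of members in brackets), with exact 95% intervals; ticks give each replicate's own list and can coincide, and the dotted line marks all protein-coding genes at 24.2%. The ribosomal protein list stands at 67.7% and the cuticle list at 4.03%.

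Several core promoter motifs and A/T-rich words, the latter described below, were more frequent at summits than in flanks. The TATA box consensus was present at 6.10% of summits against 3.91% of flanks, a ratio of 1.56 (exact sign test, adjusted p = 6.27e-12). Against dinucleotide-shuffled windows the difference was smaller, with 6.10% against 5.28%, a ratio of 1.15 (exact sign test, adjusted p = 0.0134). The TATA call was kept with non-promoter peaks only, so the difference from flanks was not confined to promoters. Non-promoter summits were 62.3% A/T against 56.6% in their flanks, and they alone were not compared with shuffled windows. Whether base composition accounts for the call there was not tested. The GAGA motif, bound by Trl and Clamp, was at 3.87% against 2.72% (exact adjusted p = 2.93e-05), the GATA motif at 17.9% against 15.7% (adjusted p = 0.000145), and the DRE, bound by Dref and BEAF-32, at 0.679% against 0.312% (adjusted p = 0.000969). The CTCF core, Ohler motifs 6 and 7, the Initiator and the NFIL3/vri motif were also more frequent, with exact adjusted p-values of 0.00118 to 0.0484. Of these 9 calls, 6 were kept with windows of 51 bp. Ohler 7, CTCF and NFIL3/vri were lost there (exact adjusted p of 0.109 to 0.275). Their log2 ratios were 0.301, 0.470 and 0.332, from 0.382, 0.615 and 0.383 in the main test. With the flank centred 500 bp away 5 were kept, and GATA, Ohler 7, NFIL3/vri and the Initiator were lost (exact adjusted p of 0.0892 to 0.244). The log2 ratios of these 4 were then 0.089, 0.176, 0.237 and 0.107, from 0.191, 0.382, 0.383 and 0.168. Ohler 7 was also lost with only the peaks shared by all 3 replicates (exact adjusted p = 0.0675). Motifs of Zelda, Su(H), ftz-f1 and Sp/KLF were less frequent at summits, with ratios of 0.200 to 0.665. With the flank centred 500 bp away the Zelda and Sp/KLF calls were lost (exact adjusted p = 0.0661 and 0.665). Their log2 ratios were −0.68 and −0.15 there, from −0.81 and −0.59. With windows of 51 bp the ftz-f1 call was lost (log2 ratio −2.50, from −2.32, exact adjusted p = 0.102). With dinucleotide-shuffled windows Sp/KLF turned to more frequent (ratio 2.85, exact adjusted p = 8.78e-05), Su(H) turned (log2 ratio 0.033) without passing the threshold, and Zelda and ftz-f1 were not past it (exact adjusted p = 0.482 and 1). The other 13 motifs did not pass the threshold, and among them the EcR/usp inverted repeat was present at 1 summit and 8 flanks (exact adjusted p = 0.0725). The homeodomain motif, another of the 13, depended on the setting. It was more frequent at summits with the peaks shared by all 3 replicates (log2 ratio 0.66, exact adjusted p = 2.46e-07), with the 500 strongest peaks (1.27, exact adjusted p = 0.00747) and without each replicate in turn (0.40 to 0.61), and less frequent than in dinucleotide-shuffled windows (−0.30, exact adjusted p = 3.72e-05). M1BP motif 1, su(Hw), the CACGTG E-box, ttk, the Ohler 5 E-box, Pho and STAT were also past the threshold in some alternatives. The GAGA, CTCF and Initiator differences were not past the threshold with only the peaks shared by all 3 replicates (log2 ratios of 0.071, 0 and 0.035), nor with the peaks shared by the remaining replicates when 1 was left out, so leaving out a replicate cannot be named as the cause. GAGA and CTCF turned without replicate 1 (log2 ratios of −0.17 and −0.081, not past the threshold). In contrast, against promoters of unbound genes GAGA rose to 1.74 and CTCF to 1.35 (exact adjusted p = 8.25e-19 and 0.00123), and against dinucleotide-shuffled windows to 1.66 and 1.63 (exact adjusted p = 8.81e-44 and 9.38e-16). Against dinucleotide-shuffled windows GATA and NFIL3/vri were less frequent, past the threshold (log2 ratios of −0.13 and −0.38, exact adjusted p = 0.00155 and 0.0137). Against promoters of unbound genes GATA was also less frequent (−0.23, exact adjusted p = 0.0140), and TATA (−0.30), DRE (−0.35), NFIL3/vri, Ohler 6, the Initiator, Sp/KLF and Su(H) turned without passing it.

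Against flanks, the 8-base words that marked summits were mostly runs of A or T with few other bases. The word AAAAAAAA was found only at the summit in 353 pairs of windows and only in the flank in 206 on 2L and 2R, and in 803 against 459 on the other chromosomes (exact sign test, adjusted p = 2.58e-21). All 10 words found on 2L and 2R passed the test on the other chromosomes. With discovery on the other chromosomes instead, 4 of the 10 words were the same, GAGCGAGA was not among them, and 1 word, AAAAAAGA, did not pass on 2L and 2R (exact adjusted p = 0.0582). Of the first 10 words, 9 had at most 1 C or G, and the remaining word, GAGCGAGA, was found only at the summit in 88 pairs and only in the flank in 30 on 2L and 2R, where it was chosen (ratio 2.93), with a ratio of 1.52 on the other chromosomes (exact adjusted p = 0.00399). Against dinucleotide-shuffled windows, an alternative added after the data were seen, only 2 of the 10 words were the same, AAAAAAAA and GAGCGAGA. The first word there was CACACACA (204 against 28 on the other chromosomes, exact adjusted p = 3.45e-33), and most of the others held C or G, so the A/T-rich character of the words depends on the background.

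Peaks had similar densities on the large chromosome arms and were nearly missing from chromosome 4. The conservative list had 82.2 peaks per Mb on 2L, 77.4 on 2R, 87.2 on 3L, 76.1 on 3R and 89.5 on X. Chromosome 4, the small chromosome rich in heterochromatin, had 3 peaks, or 2.23 per Mb. Their summits lay at 505333, 519629 and 1027276. The replicates' own lists gave 2.23 ± 1.48 per Mb (SD, n = 3) on chromosome 4 and 58.7 ± 9.81 on X, and no peak on Y.

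The region around *CG6163* itself was among those with the most peaks in the genome. Extra copies of this region, carried by the insertion that makes the fusion protein, may contribute. The density therefore does not by itself show binding of the protein at its own gene. *CG6163* lies on the minus strand of 3L at 11361986 to 11364885, and its promoter held a peak at 11364750 to 11365885 with a signal of 825, ranked 319 in the list and found in all 3 replicates. Within 20 kb of the gene lay 32 conservative peaks, against a median of 4 for random genes (permutation test, one-sided, p = 0.002), and 17 of the 13944 other protein-coding genes had as many. Whether these 17 include neighbours of *CG6163*, whose windows can hold some of the same peaks, was not tested. The replicates' own lists had 25, 38 and 24 peaks within 20 kb of *CG6163*, against medians of 2, 3 and 2 (permutation p = 0.001 each, the smallest possible). The strongest peak in this window had a signal of 1495, ranked 91. In the ranked lists without a threshold the excess was smaller, with 64, 59 and 53 peaks against medians of 28, 27 and 34, and did not pass 0.05 in replicate 3 (permutation p = 0.021, 0.029 and 0.056).

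**Figure D4:**
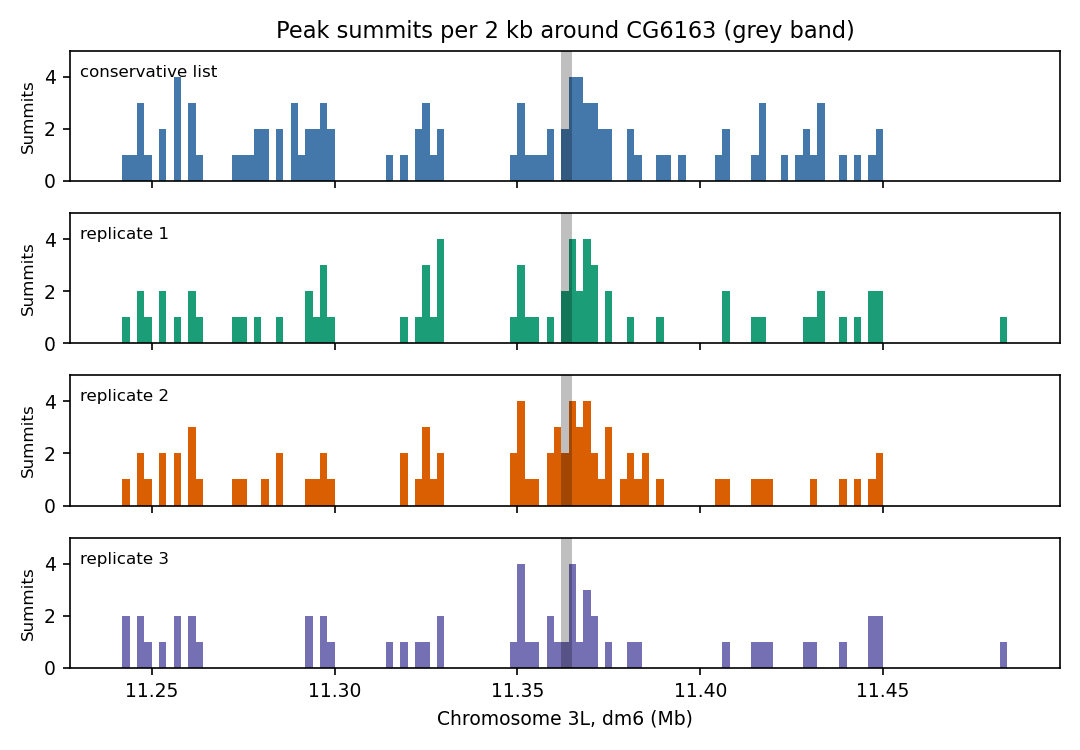
Peak summits per bin of 2 kb along chromosome 3L (Mb) around *CG6163* (grey band), for the conservative list and the own list of each replicate. The 32 conservative summits within 20 kb lie on both sides of the gene, with 25, 38 and 24 in the replicates. Extra copies of the region carried by the insertion may contribute to these numbers.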

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

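The IDR limit of 0.001, 1 peak per merged region, the q-value limit and the shuffled windows for words were chosen after the data were seen, and the cause of the changes below was not tested unless stated. The promoter share stayed above random placement in every alternative run (46.2% against 23.6% at random with a window of 1000 bp, for example), and overlap between replicates stayed between 61.7% and 76.6%. An IDR limit of 0.001 lowered the mean number of peaks per library to 4337 and the peaks per Mb to 50.9 on 2L, 48.7 on 2R, 53.6 on 3L, 46.1 on 3R and 56.0 on X, by construction. Peaks shared by all 3 libraries numbered 10332 when ranked lists were searched, which hold many more peaks. The mean Spearman coefficient was 0.757 over the union of the thresholded lists. Against peaks below the threshold, the 5' UTR share differed by a log2 ratio of 0.16 and was not past the threshold. The number of gene lists called fell to 2 with peaks shared by all 3 libraries and ranged from 2 to 7 without each replicate, with 2 when replicate 1 or replicate 2 was left out; the ribosomal protein and cuticle lists were the ones kept. Leaving out a replicate also changed the peak set from the conservative list to the peaks shared by the remaining libraries, so the effects of the 2 changes are not separated. The autophagy call was lost with the nearest start within 5 kb and on the series lists of 9110 and 8933 peaks, and the Hox and segmentation call on those 2 lists, at an IDR limit of 0.001 and at a q limit of 0.05. With the nearest start within 5 kb, the mitochondrial ribosomal list turned (log2 odds ratio −1.36). Against matched random lists 8 lists were called, of which 4 were among the main calls. Enriched motifs numbered 3 against promoters of unbound genes, 5 for non-promoter peaks and 3 for the 500 strongest peaks, against 9 in the main test. Log2 ratios that turned were, with shuffled windows, 1.11 for the Ohler 5 E-box, −0.30 for homeodomain, −0.13 for GATA, −0.38 for NFIL3/vri, 1.51 for Sp/KLF and 0.033 for Su(H). Against promoters of unbound genes they were −0.35 for DRE, −0.055 for Ohler 6, −0.23 for GATA, −0.21 for NFIL3/vri, −0.30 for TATA, −0.049 for the Initiator, 0.23 for Sp/KLF and 0.16 for Su(H). For non-promoter peaks they were −0.018 for Ohler 7 and −0.048 for the Initiator, for peaks shared by all 3 libraries 0.47 for STAT, and for the 500 strongest peaks −1.49 for GAGA and −1.14 for CTCF. Without each replicate in turn, ratios ranged from −0.17 to 0.16 for GAGA, −0.081 to 0.16 for CTCF and 0.19 to 0.42 for STAT, and turned without replicate 1. Of 736 values under an alternative, 23 turned, counting a change of sign only where the main or the alternative value was past its threshold. No paired analysis was possible because there was 1 group.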

Other observations

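Genes with more transcript starts were bound more often: 17.0% of 10246 protein-coding genes with 1 start, 36.2% of 2566 with 2 and 61.9% of 1133 with at least 3. A rise follows from the definition, since each further start adds sequence in which a summit counts. How much of the rise this accounts for was not tested. By kind of gene, 24.2% of protein-coding genes had a summit within 500 bp of a start, 13.7% of 3261 ncRNA genes, 14.8% of 290 tRNA genes (95% interval 10.9 to 19.4), 6.69% of 269 snoRNA genes and 2.99% of 268 pseudogenes. Stronger peaks had summits richer in A and T: the 500 strongest summits were 68.6% A/T against 56.1% in their flanks, all summits 60.9% against 57.0%, and ranked peaks below every threshold 52.6% against 55.6%. At promoters the difference was small (58.5% against 57.4%).

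Several other regions also held runs of dense peaks, scored as merged regions per bin of 2 kb above 3 times the genome mean, a measure chosen after the data were seen. The run with the highest score lay at 3L 530001 to 838000, with 124 merged regions over 308 kb and 32 protein-coding genes, among them *emc*, *klar* and *Hipk*. The run that holds *CG6163* was next, at 3L 11242001 to 11450000, with 91 merged regions over 208 kb. Others covered *Mnt* and *Tlk* on X (47 regions), *Smr* on X (44 regions), *sbb* on 2R (35 regions) and *tou* on 2R (36 regions). The highest-scoring run and the one at *CG6163* ranked 1 and 2 in each replicate's own list. These genes were named after their values were seen.

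All tests in the paragraphs below were chosen after the patterns were seen; those of transcript starts and of repeat content were written before their own result was known. The density of peaks around *CG6163* is a pattern for which no biological explanation was tested. A high number of transcript starts is argued against, since *CG6163* had 5 starts within 20 kb and 0 of the 300 genes most alike in that number had as many peaks (25 at most, against 32). Repeated entry of one region is also argued against, because 28 merged regions remained and 18 of the 13944 other genes, a share of 0.00129, had as many. Extra copies of the region carried by the inserted construct may contribute. Within 20 kb lay 27 peaks away from promoters, above the 99th percentile of 14 over other genes. That count cannot decide, because dense binding without extra copies would give it too. A run elsewhere scored higher with no insertion named there by the labels, which does not address copies at *CG6163*. The part of extra copies stays open, as the extent of the construct is not given in the sources used here.

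Chromosome 4 was short of peaks in the ranked lists too, with 34, 24 and 6 peaks in the 3 replicates, 40 of these 64 between 500001 and 530000. Removal of regions between the ranked and thresholded lists is argued against as the cause. Ranked peaks per Mb were already at most 0.0489 of those on the lowest of X and the large arms. That comparison cannot address a filter applied before the ranked lists were made, which was not tested and stays open. Y, left out of that comparison, had fewer still (3.27 per Mb, mean of the replicates, against 15.8 on chromosome 4). Repeat content cannot be told apart from other causes here. Of 164 windows of 100 kb with a like soft-masked share on other chromosomes, 6.71% held as few ranked peaks. The median window held 47.7, against 1.58 per window on chromosome 4. A like soft-masked share elsewhere thus seldom came with so few peaks, but 6.71% fell between the limits set beforehand. No biological explanation was tested.

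The conservative list held 406 peaks with a signal under 20, with a median of 9.38. A candidate explanation is that the entry takes the rank of a stronger library peak it overlaps. Of these peaks, 97.8% overlapped another peak of the same list, whatever its signal, against 13.3% of the other peaks. A library peak of higher signal was overlapped by 100% of them, against 3.38% of the other peaks. That contrast is not a test of the explanation, because signal differs in scale between the lists. The strongest peak had 4494 in the conservative list and 1534, 1631 and 1341 in replicates 1, 2 and 3. A peak picked for a signal under 20 is thus easily exceeded by a library peak, and other peaks seldom are. In the weakest 10% of the list, 18.8% of peaks overlapped a thresholded peak in all 3 replicates, against 2.94% in the 10% above. The explanation stays open, because it was formed after overlaps of these peaks had been seen and other causes of overlap were not tested. No biological explanation was tested.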
